A study of Homo sapiens with 6 samples.

How the data were processed

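RNA of HUVEC was sequenced in 6 libraries, 3 from cells with a scrambled shRNA and 3 from cells with an shRNA against SENCR. Per the labels' protocols, the cells were used at passage 2 to 4 and about 80% confluency, were tracked until GFP was seen throughout, and gave total RNA that was made into libraries with a strand-preserving mRNA kit. The deposited table held raw read counts per gene, which the authors made from their reads, with 1 column per library and no pooling of replicates. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.0p3 with featureCounts, and the genome build GRCh38.p7. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping genes or of near-identical copies are therefore uncertain.

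The table named 56269 genes by symbol, of which 30098 had a count in at least 1 library, and totals ran from 32649345 to 41829827 counts. Gene positions, exons, 3' UTRs, GC content and transcript lengths came from GENCODE 29 on GRCh38, to which 36071 of the symbols were matched directly, 731 through an older or newer symbol and 19467 not at all. Groups came from the labels. No column was left unused.

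Counts were scaled by TMM, filtered by expression within groups (filterByExpr, with SENCR kept in any case), and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with robust dispersion, without covariates. P-values were adjusted by Benjamini-Hochberg over the 15486 genes tested, with a threshold of 0.05. SE of a log2 fold change is the fold change divided by the square root of the test's F value, and 95% intervals are the estimate plus and minus 1.96 SE. Levels are TMM-scaled CPM, the usual counts relative to the library total. The biological coefficient of variation was 3.23%. The exact permutation tests used log2 of CPM plus 0.5.

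Before the data were examined, the groups, the main test, the processing alternatives, 30 gene lists, 4 genes to report in any case (SENCR, FLI1, CKAP4 and CDH5) and the rule for named genes were fixed. The rule took, among genes past the threshold with a mean normalized count of 50 or more, a gene symbol that is not a clone name, and no overlap between the groups, the 10 with the largest rise and the 10 with the largest fall. It also took up to 4 members of each list with the smallest p among those past the threshold, and part of these are described; some genes that the rule takes are not reported here. Genes of the sex chromosome Y and XIST were not named.

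Lists with 5 or more tested members were compared with all other genes by camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. For each list, genes past the threshold were counted over all genes tested and again adjusted over the list alone.

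The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no expression filter, a mean of at least 50 counts, the replicate number as a block, each library left out in turn, a fold change above 1.5, and, for lists, an estimated correlation. Alternatives for tables of normalized values did not apply to counts. Removal of each library's trend with GC content and transcript length (loess, span 0.5, over genes with log2 CPM above 1; 89.4% of tested genes had both values) and leaving out genes with a named heptamer in the 3' UTR were chosen after seeing the data.

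For the heptamers, each of 16383 sequences of 7 bases found in at least 20 annotated 3' UTRs was tested over 12613 genes. The signed test statistic of each gene was regressed on the presence of the heptamer with 3' UTR length, 3' UTR GC content and expression level and their squares as covariates, in Python 3.11.15 with scipy 1.17.1.

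The tests were run on simulated data first. For SENCR shRNA against scrambled shRNA, simulated over 15314 genes from the real means and library sizes, 43 of 67 genes changed 1.25-fold, 56 of 67 changed 1.5-fold and 61 of 65 changed 2-fold were called, and 11 of the 171 calls were false. In a simulation of the same comparison over 15320 genes with the unfolded protein response list lowered by a log2 of 0.20, camera called 1 of 29 lists and the list's fitted mean was -0.20. In permuted statistics of 12613 genes a planted heptamer ranked first, and without planting 0 heptamers passed. The simulated genes varied independently, and the permutation broke any link with 3' UTR composition. These runs therefore do not show how often lists or heptamers pass falsely when genes are correlated or share sequence trends.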

Results

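The data were RNA-seq read counts per gene from HUVEC, primary endothelial cells of the human umbilical vein, that carried a lentiviral short hairpin RNA (shRNA). One group of 3 libraries came from cells with a scrambled shRNA and the other group of 3 from cells with an shRNA against SENCR, a long noncoding RNA transcribed antisense to the gene of the endothelial transcription factor FLI1. Both lentiviruses carried a GFP tag, and RNA was taken about 3 days after transduction. The 6 libraries held between 32649345 and 41829827 counts. The labels do not say that the replicates came from separate donors, so the p-values measure only the spread between these libraries, which may be technical. Within each group, every pair of replicates differed beyond sampling noise (chi-square per degree of freedom 2.16 to 4.15), so no library was a second copy of another; this does not show that the cultures were separate.

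The question of the comparison was what changes in HUVEC when SENCR is knocked down. SENCR fell to 25.1% of its level in cells with the scrambled shRNA, a log2 fold change of -1.995 (SE 0.149) with an adjusted p of 3.00e-16 in edgeR's quasi-likelihood test. It was measured at 4.26 ± 0.228 CPM (TMM-scaled counts relative to the library total; SD, n = 3) with the scrambled shRNA and at 1.06 ± 0.253 (SD, n = 3) with the SENCR shRNA. The scrambled libraries held 136, 152 and 159 SENCR reads, and the SENCR shRNA libraries held 33, 56 and 32. CKAP4, an endoplasmic reticulum membrane protein, fell by 12.7% (log2 fold change -0.20, SE 0.0303, adjusted p 2.18e-06 in edgeR). FLI1 and CDH5, the gene of VE-cadherin, the adhesion protein of endothelial adherens junctions, did not pass the test. FLI1 had a log2 fold change of -0.03 (adjusted p 0.555 in edgeR) and a 95% interval of -6.37% to 1.81%. CDH5 had one of -0.01 (adjusted p 0.837 in edgeR) and a 95% interval of -4.62% to 2.92%. Mean CDH5 was 2298 ± 35.4 CPM (SD, n = 3) with the scrambled shRNA and 2277 ± 14.98 (SD, n = 3) with the SENCR shRNA. An exact two-sided permutation test of 3 against 3 libraries cannot give a p below 0.1; it gave 0.1 for SENCR, FLI1 and CKAP4 and 0.5 for CDH5.

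**Figure D1:**
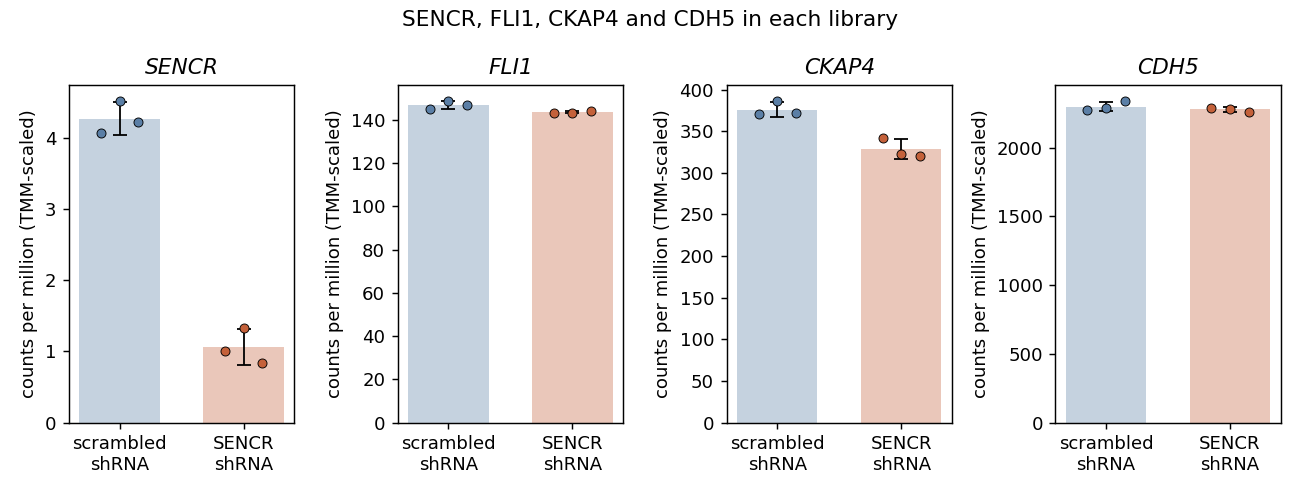
TMM-scaled CPM (y axes, each from 0) of SENCR, FLI1, CKAP4 and CDH5 in the 3 scrambled shRNA and 3 SENCR shRNA libraries; points are libraries, bars are group means and error bars are SD. SENCR averaged 4.26 and 1.06 CPM in the 2 groups, while the CDH5 means were 2298 and 2277.

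In GENCODE 29 on GRCh38, SENCR (ENSG00000254703.2, annotated as antisense) lies on chromosome 11 from 128691672 to 128696023 on the minus strand. All of it lies inside the span of FLI1 (ENSG00000151702.16), which runs from 128686535 to 128813267 on the plus strand. SENCR has 3 exons with 1298 bases, of which 162 overlap FLI1 exons on the opposite strand. The library kit keeps the strand, but the strand setting of the read counting is not given in the sources used here, so reads in the shared bases are uncertain for either gene. The 7 measured genes of the list of SENCR's chromosomal neighbours did not change as a list (camera adjusted p 0.384), and 2 of them rose, 3 rising and 1 falling when adjusted over the list alone.

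**Figure D2:**
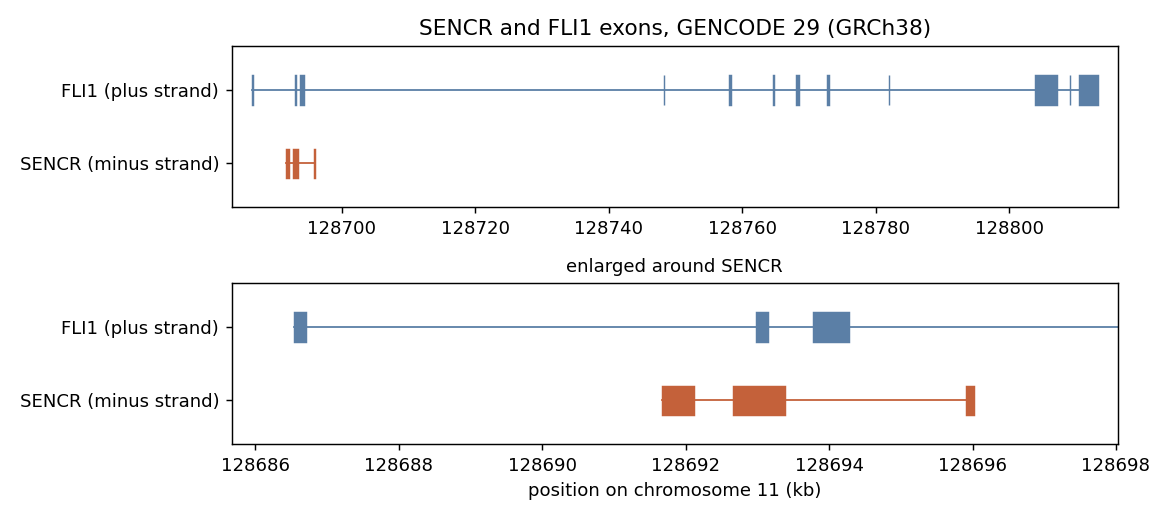
Exons (boxes) of FLI1 and SENCR along chromosome 11 in kb, from GENCODE 29 on GRCh38, with the whole of FLI1 above and the part around SENCR enlarged below. SENCR, on the minus strand, overlaps FLI1 exons in 162 of its 1298 exonic bases.

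Across the transcriptome, 776 genes rose and 1033 fell with the SENCR shRNA among 15486 tested, at an adjusted p under 0.05 in edgeR. Most changes were small: the median absolute log2 change of the called genes was 0.17, and only 25 genes rose and 52 fell by more than 1.5-fold. After SENCR itself, the genes named by rule that fell included RPPH1, the RNA of ribonuclease P (log2 fold change -1.52), the lysosomal carboxypeptidase CTSA (-1.10) and the leukocyte adhesion molecule ICAM1 (-1.02). The chemokine CCL2 (49.99% of its level with the scrambled shRNA), E-selectin (SELE, log2 fold change -0.96), the collagen receptor MRC2 (-0.94) and RND1 (-0.86) fell as well. CTSA went from 155.0 ± 3.90 to 72.3 ± 5.86 CPM, and MRC2 from 68.2 ± 2.18 to 35.5 ± 1.28 (SD, n = 3 each). Among genes named by rule, the keratin KRT15 (1.04), DNAH8 (0.78), tissue plasminogen activator (PLAT, 0.70), AK5 (0.68) and NLGN3 (0.66) rose most. PLAT went from 39.4 ± 2.59 to 63.9 ± 2.02 CPM (SD, n = 3 each). SLC7A8 (0.63), EPHB6 (0.64), PTPN22 (0.56) and TMEM158 (0.54) rose as well, and MEGF10 (0.65) rose with all libraries but had an adjusted p of 0.0537 in edgeR without SENCR shRNA replicate 2. Of these falls, CTSA, CCL2 and MRC2 each have 1 copy of the heptamer GCCCTTT, which also lies in SENCR, in the annotated 3' UTR, and so do AK5 and TMEM158 among the rises. Of the list members described, ATF6, CCNB2, EFNB2, FLT1, MMP1, NECTIN3, PTPRB and TXNIP, which all fell, have 1 copy too, and DLL4, which fell, has 2. Of these genes, RPPH1 overlaps AL355075.4 on the same strand, and on the opposite strand SELE overlaps C1orf112, ICAM1 overlaps AC011511.2, CTSA overlaps NEURL2 and MRC2 overlaps AC080038.3. CKAP4, AK5, DNAH8, KRT15, PTPN22 and SLC7A8 overlap other annotated genes too, so all these counts are uncertain where reads are shared. The count of higher genes was 437 without scrambled shRNA replicate 1, 443 without scrambled shRNA replicate 2 and 442 without SENCR shRNA replicate 2, and that of lower genes was 659 without SENCR shRNA replicate 2. The values of the 2 groups did not overlap in 26.7% of the tested genes, where chance gives 10%.

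**Figure D3:**
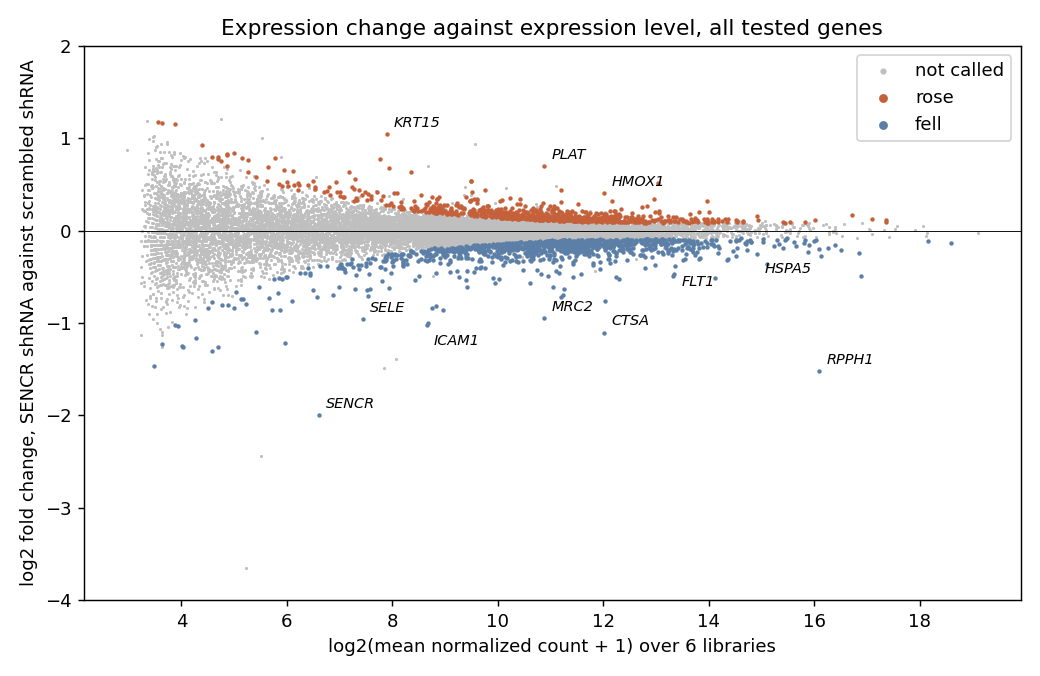
Log2 fold change of SENCR shRNA against scrambled shRNA (y axis) against log2 of the mean normalized count plus 1 over the 6 libraries (x axis), 1 point per tested gene (chromosome Y and XIST left out), coloured where the adjusted p was under 0.05. SENCR lies at -1.995 and RPPH1 at -1.52, while most of the 1809 called genes lie close to 0, with a median absolute change of 0.17.

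Part of the inflammatory genes of the endothelium were lower with the SENCR shRNA. In the list of NF-kappaB targets, 13 of 25 measured genes fell and 1 rose, and 16 fell and 1 rose when adjusted over the list alone. The mean log2 change was -0.39 (camera adjusted p 9.06e-09; adjusted p = 0.285 with an estimated correlation). The chemokines CXCL1 (-0.81, SE 0.0703) and CXCL8 (-0.49, SE 0.0429) fell beside CCL2 and ICAM1. IL6, picked out after its value was seen, was the 1 member that rose (0.37, SE 0.0978).

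Genes of protein folding in the endoplasmic reticulum fell together by small amounts. In the unfolded protein response list, 19 of 24 measured genes fell and none rose, and 23 fell when adjusted over the list alone. The fitted log2 change was below 0 for all 24. The mean change was -0.17 (SE over genes 0.0120; camera adjusted p 2.02e-15; adjusted p = 0.153 with an estimated correlation). The chaperones HSPA5 (-0.25, SE 0.0285) and HSP90B1 (-0.23, SE 0.0287), the degradation factor SEL1L (-0.26, SE 0.0305) and the stress sensor ATF6 (-0.23, SE 0.0313) were among those that fell. HSPA5 went from 924 ± 23.1 to 779 ± 7.78 CPM (SD, n = 3 each). CKAP4 is a member of this list too. The integrated stress response list did not pass (camera adjusted p 0.108), with 1 gene that rose and 5 that fell of 26, and 1 and 7 when adjusted over the list alone. Without SENCR shRNA replicate 1 its adjusted p was 0.0171, and once trends with GC content and transcript length were removed, an alternative chosen after seeing the data, it was 0.00498 (mean log2 change -0.077 against -0.071). In the heat shock list 1 of 12 genes fell, also when adjusted over the list alone (camera adjusted p 0.275).

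Part of the cell cycle genes rose. In the list of DNA replication and S phase genes, 13 of 39 rose and none fell, and 17 rose when adjusted over the list alone. Their mean log2 change was 0.13 (camera adjusted p 1.15e-08; adjusted p = 0.153 with an estimated correlation). The replicative helicase subunits MCM2 (0.33, SE 0.0551) and MCM5 (0.29, SE 0.0441) and thymidine kinase TK1 (0.29, SE 0.0441) were among them. In the G2/M list 19 of 41 rose and 1 fell, and 21 and 1 when adjusted over the list alone. The mean was 0.10 (camera adjusted p 2.14e-07; adjusted p = 0.442 with an estimated correlation). The proliferation marker MKI67 rose (0.23, SE 0.0336) and so did BIRC5 (0.21, SE 0.0405), whereas the cyclin CCNB2 was the member that fell (-0.41, SE 0.0541). CCNB2 is among the carriers of GCCCTTT, and without its 3 carriers the G2/M list had a mean of 0.115.

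Matrix and vessel growth genes were lower on balance. In the basement membrane and matrix list 16 of 31 fell and 1 rose, and 19 and 1 when adjusted over the list alone (mean log2 change -0.12; camera adjusted p 2.14e-07; adjusted p = 0.285 with an estimated correlation). COL8A1 (-0.56, SE 0.0468), the collagenase MMP1 (-0.24, SE 0.0291), SPARC (-0.19, SE 0.0283) and MGP (-0.22, SE 0.0338) fell. In the angiogenesis and tip cell list 11 of 25 fell and 3 rose, and 13 and 3 when adjusted over the list alone (mean -0.08; camera adjusted p 0.000573; adjusted p = 0.285 with an estimated correlation). The VEGF receptor FLT1 (-0.38, SE 0.0307), ESM1 (-0.30, SE 0.0324), the Notch ligand DLL4 (-0.31, SE 0.0373) and NRP2 (-0.21, SE 0.0291) fell. In the Notch list 7 of 18 fell and 1 rose, with the same counts adjusted over the list alone (mean -0.19, median -0.03; camera adjusted p 0.0453; adjusted p = 0.544 with an estimated correlation). EFNB2 (-0.41, SE 0.0338) and JAG2 (-0.23, SE 0.0365) were among those that fell. In the TGF-beta and BMP list 7 of 22 fell and none rose, and 8 fell when adjusted over the list alone (mean -0.09; camera adjusted p 0.00330; adjusted p = 0.561 with an estimated correlation). The receptors TGFBR1 (-0.20, SE 0.0448) and TGFBR2 (-0.13, SE 0.0284) fell. Against the average of the 6 libraries, this list's mean log2 deviation was 0.021, -0.080 and -0.073 in SENCR shRNA replicates 1, 2 and 3. In scrambled shRNA replicates 1, 2 and 3 it was 0.024, 0.034 and 0.074. SENCR shRNA replicate 1 thus lay close to scrambled shRNA replicate 1. The Notch list did not pass without scrambled shRNA replicate 3 (adjusted p 0.230) or SENCR shRNA replicate 3 (0.0855), nor with the replicate number as a block (0.0509). When genes with GCCCTTT in the 3' UTR were left out, an alternative chosen after seeing the data, neither the angiogenesis list (camera adjusted p 0.0692) nor the Notch list (0.161) passed. The angiogenesis mean shrank from -0.081 (SE over genes 0.0308) to -0.041 (SE 0.0333) without its 6 carriers. The Notch mean was about as large, -0.193 (SE 0.1004) with all members and -0.185 (SE 0.119) without its 3 carriers. Its median went from -0.034 to 0.0069, so the mean without carriers rested on part of the genes. The carriers left out included EFNB2 and DLL4, the Notch members with the smallest p in edgeR. GJA4, without a copy, had a log2 change of -1.26 (SE 0.282) at a mean normalized count of 24.7. Camera weighs t statistics and not log2 changes, so the mean could stay while the call was lost.

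Endothelial identity genes were slightly lower on balance. In that list 10 of 38 fell and 2 rose, and 11 and 4 when adjusted over the list alone (mean log2 change -0.06; camera adjusted p 0.00892; adjusted p = 0.298 with an estimated correlation). Without scrambled shRNA replicate 3 its adjusted p was 0.0661. FLT1 (-0.38, SE 0.0307), MMRN1 (-0.27, SE 0.0293) and PECAM1 (-0.21, SE 0.0282) fell, and the endothelial nitric oxide synthase NOS3 rose (0.20, SE 0.0326). The adherens junction list did not pass camera (mean -0.02, adjusted p 0.612). In it 2 of 20 rose and 3 fell, and 3 and 4 when adjusted over the list alone. NECTIN3 (-0.25, SE 0.0422) and PTPRB (-0.18, SE 0.0289) were among those that fell. The tight junction list did not pass either (camera adjusted p 0.209), with 6 of 20 that fell and 1 that rose, also when adjusted over the list alone. Its mean was -0.17 and its median -0.0044, and JAM2 (-0.61, SE 0.119) fell while CLDN11 (0.18, SE 0.0340) rose. In the shear-responsive list (camera adjusted p 0.536) 3 of 16 rose and 2 fell, and 3 and 3 when adjusted over the list alone. HMOX1 (0.40, SE 0.0331) and thrombomodulin, THBD (0.22, SE 0.0368), rose, and TXNIP fell (-0.52, SE 0.0338).

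**Figure D4:**
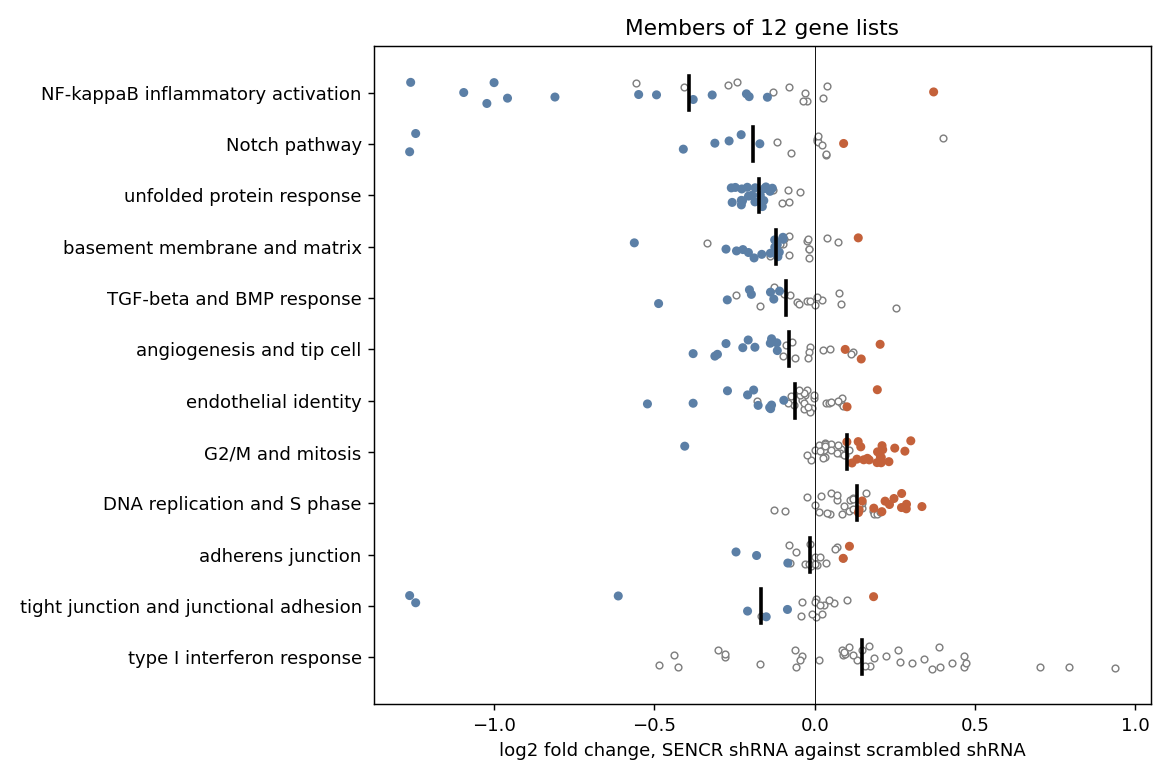
Log2 fold changes of SENCR shRNA against scrambled shRNA (x axis) for the measured members of 12 of the gene lists, 1 point per gene, filled where the adjusted p over all genes was under 0.05 and open otherwise; black bars are list means. All 24 points of the unfolded protein response list lie below 0, and the adherens junction list has its mean at -0.02.

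None of the lists for other cell types passed camera. Smooth muscle (2 of 12 fell), fibroblast and pericyte (2 of 9 fell), epithelial (1 of 5 fell) and lymphatic endothelial markers (1 of 9 rose and 1 fell) had camera adjusted p of 0.981, 0.734, 0.734 and 0.438. Adjusted over the list alone, these counts were 1 rise and 3 falls, 1 rise and 2 falls, 1 fall, and 1 rise and 1 fall, and only 1 leukocyte marker was measured. MCAM, a pericyte marker that endothelial cells also express, fell (-0.20, SE 0.0287). Mesenchymal transition genes (8 of 22 fell, also when adjusted over the list alone; camera adjusted p 0.0825) passed only without SENCR shRNA replicate 1 (adjusted p 0.00362). CTGF (-0.36, SE 0.0342) and TNC (-0.72, SE 0.137) fell in that list.

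In the interferon list none of 39 genes passed in edgeR, over all genes or adjusted over the list alone, and the mean was 0.15 (camera adjusted p 0.690). Its mean was -0.35 without SENCR shRNA replicate 1 (camera adjusted p 4.10e-07) and 0.40 without SENCR shRNA replicate 3 (camera adjusted p 0.00368). Camera asks whether a list shifts one way, so a list with changes in both directions can fail to pass. Integrins and focal adhesion (4 of 26 rose and 5 fell, camera adjusted p 0.612) did not pass. Nor did YAP/TAZ targets (1 of 21 rose and 4 fell, 0.305). Hypoxia and glycolysis genes (1 of 31 rose and 4 fell, 0.438) did not pass camera. Adjusted over the list alone, 7 rose and 6 fell, 1 rose and 4 fell, and 1 rose and 4 fell. ITGAV (-0.32, SE 0.0342), CRIM1 (-0.28, SE 0.0286) and SLC2A3 (-0.23, SE 0.0335) were among those that fell. The p53 targets (2 of 26 rose and 5 fell, camera adjusted p 0.438) did not pass either. Nor did cholesterol biosynthesis genes (2 of 23 rose and 2 fell, 0.612). Immediate early genes (1 of 22 rose and 2 fell, 0.619) did not pass camera. Adjusted over the list alone, 5 rose and 7 fell, 2 rose and 2 fell, and 2 rose and 2 fell. JUNB (-0.27, SE 0.0506) fell. The mean (-0.04) and median (0.03) of the immediate early list differed in sign. The smooth muscle list had a mean of 0.0017 and a median of -0.04, and the epithelial mean was 0.02. No replication-dependent histone of 8 passed, also when adjusted over the list alone (camera adjusted p 0.612), and 2 of 13 mitochondrially encoded genes fell, also when adjusted over the list alone (camera adjusted p 0.305).

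Of the 29 lists tested, 9 passed camera with a preset correlation of 0.01 between genes, and with an estimated correlation 0 passed. By fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, 8 of the 9 had adjusted p from 0.00326 to 0.0464 and the TGF-beta list had 0.0559. Of the 20 lists that did not pass camera, the integrated stress response list passed fry (adjusted p 0.0464).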

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

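Removal of GC content and transcript length trends, and leaving out genes with the heptamer GCCCTTT in the 3' UTR, were chosen after seeing the data; the other alternatives were fixed before. The log2 fold change of SENCR kept its direction and its side of the threshold in every alternative that gave an adjusted p, from -1.84 to -2.22 with a library left out. DESeq2 gave SENCR a log2 fold change of -2.002 but no adjusted p, because its mean count of 96.2 lay under that tool's filter at 168. Requiring a fold change above 1.5 left 25 higher and 52 lower genes by construction. With a library left out, higher genes ranged from 437 to 841 and lower genes from 659 to 1139, with fewer samples in each fit. Under the other scalings, tests, filters and corrections, higher genes ranged from 544 to 958 and lower genes from 781 to 1092. Leaving out carriers of the heptamer, with the adjusted p of the main fit kept, left 703 higher and 698 lower genes by construction. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.089, -0.046 and -0.229, and 0 of 6 libraries correlated best with their own number. The fit with the replicate number as a block called 700 higher and 956 lower genes and 8 lists. Lists that changed numbered 0 with an estimated correlation in place of the preset one, 7 to 12 with a library left out, 7 without carriers of the heptamer and 10 without the GC and length trends. Of 104 named genes past the threshold, 10 had no adjusted p in DESeq2 and 1 had none with a mean of at least 50 counts required. Of the 94 with an adjusted p in every fit, 73 kept their side and direction in all of them, and 0 of the 104 reversed where they had a value. List means that changed sign with a library left out ranged from -0.0069 to 0.034 for epithelial markers, from -0.079 to 0.062 for histones, from -0.012 to 0.028 for the shear-responsive list, from -0.0071 to 0.019 for smooth muscle and from -0.35 to 0.40 for interferon. The smooth muscle mean was -0.0061 without the GC and length trends. The cause was not tested for these. Depth limits SENCR most among the 4 genes fixed beforehand, with 32 to 159 reads per library.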

Other observations

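The 8 gene lists of the next paragraph, the splits of the libraries, the tests on genes without the heptamer and the removal of GC and length trends were chosen only after the results had been seen. So were the comparison of the top heptamers with unrelated ones, without which the heptamer of the rises would have met its test, and the leave-one-out and per-library values of the short RNAs.

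Part of the genes of the secretory and lysosomal system were lower with the SENCR shRNA. In a lysosome list 20 of 36 genes fell and none rose (mean log2 change -0.16; camera adjusted p 1.31e-11; adjusted p = 0.124 with an estimated correlation). CTSA (-1.10), the thioesterase PPT1 (-0.72) and LAMP1 (-0.17) were among them, and the 33 members without the heptamer GCCCTTT in the 3' UTR had a mean of -0.12 (camera adjusted p 1.06e-10). Of vesicle coat and Golgi genes 15 of 38 fell, such as LMAN1 (-0.26) and COPZ1 (-0.24), and of translocon and N-glycosylation genes 14 of 41 fell, such as TRAM1 (-0.26) and RPN2 (-0.21). Their camera adjusted p were 2.48e-09 and 4.28e-07, with adjusted p = 0.124 and 0.166 with an estimated correlation. Of collagen processing genes 11 of 22 fell, among them PLOD2 (-0.32) and the collagen chaperone SERPINH1 (-0.30), with a camera adjusted p of 6.81e-06 and adjusted p = 0.124 with an estimated correlation. In coagulation and fibrinolysis 8 of 21 genes fell and 4 rose (camera adjusted p 0.0316, and 0.325 with an estimated correlation). The mean log2 change of that list was -0.045 (SE over genes 0.0580), and it did not pass fry (adjusted p 0.264). The protease activator PLAT (0.70), the inhibitor TFPI2 (0.52), THBD (0.22) and S100A10 (0.12) rose, and MMRN1 (-0.27) and SERPINE2 (-0.25) fell. Cytosolic ribosomal proteins passed with a mean of 0.03 (camera adjusted p 0.00230, adjusted p = 0.576 with an estimated correlation). Of these genes 3 of 75 rose, and none when adjusted over the list alone. Their fry adjusted p was 0.264. The respiratory chain (1 of 50 rose and 2 fell; camera adjusted p 0.247) and short RNAs without a poly(A) tail (0 of 7 passed in edgeR; 0.189) did not pass.

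The type I interferon genes differed between libraries of the same group. The list's mean log2 deviation from the average of the 6 libraries was 0.81, -0.18 and -0.57 in SENCR shRNA replicates 1, 2 and 3, and -0.09, -0.14 and 0.17 in the scrambled shRNA replicates.

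Part of the genes that fell have a short sequence in common. Of 16383 heptamers tested over 12613 genes with a 3' UTR, carriers of GCCCTTT fell most (t = -17.3, 1866 carriers). The next heptamer without a shared run of 6 bases, ATTATTG, had t = -5.31. GCCCTTT was in the 3' UTR of 33.5% of the 998 genes called lower and of 13.2% of the other genes, shares of the same genes by which the heptamer was picked. All 20 of the called falls with the smallest p and an annotated 3' UTR had it, among them MRC2, ANTXR2, PPT1, RSL24D1, RTN4 and LBR. Of genes without it 6.18% were called lower and 6.10% higher, of genes with 1 copy 17.6% and 3.84%. Of genes with 2 or more copies these shares were 19.4% and 4.30%. The mean log2 change was -0.047 (SE 0.0045) with 1 copy and -0.056 (SE 0.0094) with 2 or more. More copies thus went with little further fall. ICAM1, SELE and HSPA5 have no copy. The heptamer occurs in the SENCR transcript at base 656 in exon 2 (chromosome 11, 128692841 to 128692847, minus strand) and at base 1283 in exon 3 (128691681 to 128691687), and 7.34% of all tested heptamers occur in that transcript.

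For the genes that fell and rose, a trend with GC content or transcript length is argued against as the whole source, since 1055 lower and 958 higher genes were called once each library's trends were removed, and 1521 of these 2013 genes were among the 1809 called before. Seed pairing of the SENCR hairpin with 3' UTRs, by which a small RNA can lower transcripts it was not designed against, is a candidate explanation for part of the falls: the heptamer whose carriers fell most passed with an adjusted p of 1.04e-61 and lies in SENCR. It was 1 of 566 whose carriers fell and that passed, so a broad sequence trend is present in the falls too, but its t of -17.3 stands apart from the -5.31 of the next unrelated heptamer. Only the longest annotated 3' UTR of each gene was searched. If these are complete, direct pairing at GCCCTTT in 3' UTRs cannot account for every fall, unless falls were passed on from carriers. Of the lower calls with a 3' UTR, 66.5% lack this heptamer, and 698 lower calls were left without its carriers. Carriers of CCCTTTA (t = -9.52), TGCCCTT (t = -9.49) and AGCCCTT (t = -9.09), which share 6 of its bases, fell too. CCCTTTA and TGCCCTT lie in SENCR, and AGCCCTT does not. Each heptamer was tested alone, so these carriers can hold GCCCTTT as well, and their t values do not show what shifted sites do by themselves. Genes with only shorter or shifted sites count as lacking the heptamer, so direct pairing through such sites stays open and untested. Falls passed on from carriers to other genes were not tested. For the rises, the heptamer whose carriers rose most, CCAGCAC (adjusted p 8.28e-07, t = 6.33), was 1 of 811 that passed and barely above the unrelated GCCACGG (t = 6.12), so pairing of the scrambled hairpin cannot be told apart from a broad sequence trend. The hairpin sequence is not given in the sources used here, and loss of SENCR itself, or another small RNA with the same seed, stays open and untested.

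The unfolded protein response list fell with a mean log2 change of -0.17, a call that was lost with an estimated correlation (adjusted p = 0.153). GC content and transcript length trends are argued against, since the mean was -0.16 after their removal. Direct pairing at GCCCTTT in the members' own 3' UTRs is argued against as the whole source. The 19 members without this heptamer had a mean of -0.17 (camera adjusted p 3.53e-13). These 19 were not checked for shorter or shifted sites, so direct pairing through such sites stays open and untested. A fall passed on from a carrier stays open and untested: the stress sensor ATF6, a transcription factor of this response, has 1 copy and fell (-0.23). A lower level of the secretory pathway as a whole is a possible explanation that stays open: the translocon and N-glycosylation list had a mean of -0.097 and the vesicle coat and Golgi list one of -0.095. Without their 6 and 5 carriers of GCCCTTT, these means were -0.066 and -0.077, smaller in size than that of the unfolded protein response list. The NF-kappaB list too kept a mean of -0.38 in its 22 members without the heptamer. A biological effect of SENCR on these genes is a hypothesis that the design, with 1 hairpin against 1 control, leaves untested.

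RPPH1 took 0.278% to 0.291% of all counts in the scrambled libraries and 0.0873% to 0.114% in the SENCR shRNA libraries. Whether a different carry-over of short RNAs without a poly(A) tail through the mRNA selection is the source stays open. The 7 others measured had a median log2 change of -1.39 (bootstrap SE 0.757), which goes with it. That median ranged from -0.56 to -2.43 with a library left out, where RPPH1 ranged from -1.43 to -1.62. None of the 7 passed in edgeR by itself, and their values ran from -3.65 to 0.37. RMRP (-3.65), RN7SK (-2.44), RN7SL2 (-1.49) and RN7SL1 (-1.39) were low, while SNORA73B (-0.28), SCARNA13 (-0.07) and SNORA81 (0.37) moved little. Depth limits the 7: their reads per library ran from 2 (RMRP) to 659 (RN7SL1), against 33357 to 105607 for RPPH1. Between the scrambled libraries, however, the median log2 deviation of the 7 from the average of the 6 libraries ranged over 2.32 while RPPH1 ranged over 0.0588, so RPPH1 did not follow them there. The others moved more than RPPH1 beyond the SE of their median in 2 of the 3 pairs of scrambled libraries and in 0 of the 3 pairs of SENCR shRNA libraries. A biological change of RPPH1 was not tested.

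The 6 libraries can be split in 10 ways, too few for a share under 0.05. For higher and for lower genes 1 of the 10 splits, the real one, gave as many: 776 and 1033 against 0 in the others. For gene lists 2 of the 10 splits gave 9 or more, the real one and 1 that mixed the groups, which also gave 9. With the preset correlation the unfolded protein response list passed in 6 of the other splits, with a mean of at most 0.08 in size against 0.17 in the real one. The NF-kappaB list passed in 3 of them, with at most 0.22 against 0.39, the matrix list in 3, with at most 0.084 against 0.119, the S phase list in 6, with at most 0.065 against 0.132, and the G2/M list in 4, with at most 0.071 against 0.1003. The TGF-beta list passed in 2 of them, with a mean of up to 0.0881 in size, close to the 0.0885 of the real split. The angiogenesis, endothelial identity and Notch lists passed in 0 of them, with at most 0.043, 0.029 and 0.145 against 0.081, 0.062 and 0.193. Every other split mixes the groups unevenly, so it keeps part of the real difference. Smaller counts and means there are partly fixed in advance. Neither a pass there nor its absence shows how specific a list is to the real split.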
